A study of Mus musculus with 8 samples.

How the data were processed

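Total RNA of mouse hearts was enriched for messenger RNA and sequenced as bulk libraries, per the labels' protocols. The labels do not say which parts of the heart were taken, and Myl7, an abundant atrial gene, was at 0.621 to 1.2 FPKM in EAM knockout 3 and both controls. The deposited table holds FPKM values for 34745 genes in 8 libraries, with gene symbols, Ensembl gene identifiers and coordinates. The submitters' processing notes name HISAT2 2.0.4, StringTie 1.3.3b and edgeR, without their roles or order, and the genome build mm10. The annotation release and any filter are not given in the sources used here. The deposited FPKM values carried no sign of a further scaling between libraries, because FPKM multiplied by exon length summed to 961237 to 965960 in the 8 libraries. Lengths for that sum came from GENCODE M21 (GRCm38), which holds 98.6% of the gene identifiers and gives the same start and end for 80.8% of them. Coordinates are printed as in the deposited table. Whether the library kit or the counting used strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart.

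Groups were taken from the labels. The 3 groups were control wild type at day 0 (n = 2), EAM wild type at day 21 (n = 3) and EAM Trim21 KO at day 21 (n = 3). A second deposited sheet pairs each library with an earlier name. These names give day 35 for both EAM groups and day 0 for control, and animal numbers 2, 5 and 6 for the knockout, 1, 3 and 4 for EAM wild type and 1 and 2 for control. The replicate numbers of the labels therefore do not pair animals across groups. The labels do not say how the libraries of a group relate to animals, and p-values measure only the spread between these libraries.

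Depth was inferred from the FPKM table. The lowest values of a library fall on steps of 1 fragment, whose size depends on exon length and depth, and 229 to 341 genes per library gave 14390000 to 16930000 fragments. At this depth 3 fragments of Il17a correspond to 0.151 to 0.178 FPKM. Such floors cover counting error only. No column of values was left unused.

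Genes were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1). Genes with an FPKM of at least 1 in at least 2 libraries entered the test, which left 10393 genes and removed 24352. All 8 libraries and 3 groups were fitted together, so that the 2 control libraries share the spread estimate of the other groups, with a mean-variance trend (trend = TRUE), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The fit had 5 residual degrees of freedom. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. For 59 symbols that occur in more than 1 row, the row with the highest mean was used in gene lists.

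A set of 49 gene lists was fixed before the data were examined, covering immune cell markers, cytokine and interferon pathways, fibroblast, vascular and muscle genes, metabolism, stress and clock genes, and markers of tissues that could be dissected along with the heart. Lists were tested with camera in limma at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 42 lists with at least 3 tested members. The estimated-correlation version of camera and fry stand beside it. Fry passed 19 lists in EAM wild type against control, 20 in EAM knockout against EAM wild type and 5 in EAM knockout against control, of which 16, 15 and 5 also passed camera. With an estimated correlation no list passed in any of the 3 comparisons, the lowest adjusted p being 0.0536, 0.133 and 0.218. List scores per library, the mean of log2(FPKM + 1) over the list, were compared between genotypes with an exact permutation test, and the lowest adjusted value was 0.183 over 42 lists.

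Genes were named by a rule written beforehand. Trim21 came first. In each comparison the 10 largest rises and 10 largest falls followed, among genes past the threshold whose groups did not overlap and whose higher group had a mean of at least 5 FPKM, leaving out gene models without a symbol. A fixed set of 22 genes and the leading members of each list that passed camera completed the rule. Hbb-bs was named beside Hbb-bt after its values were seen. Some genes that the rule names are not reported here.

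The procedure was tested on simulated data, with 200 of the 10393 genes changed and the group sizes of each comparison. A further small list of genes was shifted as well, and calls among them were not counted as false. Noise was drawn independently for each gene and library. The simulation therefore lacks the correlation between genes and the differences between libraries of the real data, and its rates need not hold there. For EAM wild type against control it recovered 90% of genes changed by a log2 value of 1 and 100% of those changed by 2, with 13 false calls among 210. For EAM knockout against EAM wild type it recovered 89% and 99%, with 6 false calls among 201.

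Alternatives covered the pseudocount, the expression filter, the scaling between libraries, the variance model, library weights, the groups in the fit, the replicate number as a block, the list test and leaving out each library. After the data were examined, the fits without 3 libraries high in atrial transcripts and with an atrial score as a covariate were added. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib.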

Results

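Messenger RNA was sequenced from mouse hearts in 8 libraries of 3 groups. Experimental autoimmune myocarditis (EAM) is an inflammation of the heart raised in mice by immunization against a cardiac myosin heavy chain peptide in complete Freund's adjuvant. The groups were 2 libraries of wild-type control hearts labelled day 0, 3 of wild-type hearts labelled day 21 of EAM, and 3 of Trim21 knockout hearts labelled day 21 of EAM. All 8 libraries carry the strain label Balb/c. TRIM21 is an E3 ubiquitin ligase that also binds antibodies in the cytosol. The study asked how TRIM21 acts in autoimmune myocarditis, with IL-17A signalling and the adaptor TRAF3 named in its title. The treatment protocol describes control mice that received adjuvant with buffer, while the labels place the control hearts at day 0, so day and immunization changed together between control and EAM. Earlier library names in the deposited workbook give day 35 for both EAM groups, against day 21 in the labels, and the difference was not resolved. Knockout hearts without EAM were not analysed here, so an interaction of genotype and disease was not tested.

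Values were FPKM, fragments scaled to exon length and to the mapped fragments of the library, for 34745 genes. The steps between low values gave a depth of 14390000 to 16930000 fragments per library, and 9201 to 9975 genes had an FPKM of at least 1. Pearson correlations of log2(FPKM + 1) across tested genes were 0.968 to 0.987 within groups and 0.958 to 0.977 between groups. Mitochondrially encoded genes took 33.6% to 43.6% of the FPKM values weighted by exon length, with the lowest share in EAM wild type 3. Atrial transcripts set 3 libraries apart. Sln, a regulator of the calcium pump in atrial muscle, was at 531.5, 421 and 395 FPKM in EAM knockout 1, EAM knockout 2 and EAM wild type 2, and at 0.119 to 58.9 FPKM in the other 5 libraries. Of 8 tested atrial genes, 7 were higher in each of these 3 libraries than in any of the other 5. The mean log2(FPKM + 1) of the 8 genes was 1.86 and 1.89 in control, 3.455, 6.95 and 4.23 in EAM wild type and 7.06, 6.48 and 1.74 in EAM knockout, so atrial transcripts were higher in each EAM wild-type library than in control. A fit without the 3 libraries leaves knockout 3 as the only knockout library, assumed to vary like the other groups, so its counts below differ in the number of samples as well as in atrial content.

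Trim21 was checked first. The gene, ENSMUSG00000030966, lies on chromosome 7 from 102557922 to 102565469 (mm10). Its FPKM was 0.0481, 0 and 0.022 in the 3 knockout libraries, the equivalent of at most 2.7 fragments. It was 2.98, 3.29 and 3.37 in EAM wild type and 1.98 and 2.18 in control. On the log2(FPKM + 1) scale, Trim21 fell by 2.04 (SE 0.10) in EAM knockout against EAM wild type (limma adjusted p = 1.52e-05). The higher level in EAM wild type than in control did not pass (log2 difference 0.45, SE 0.11, limma adjusted p = 0.0843).

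**Figure D1:**
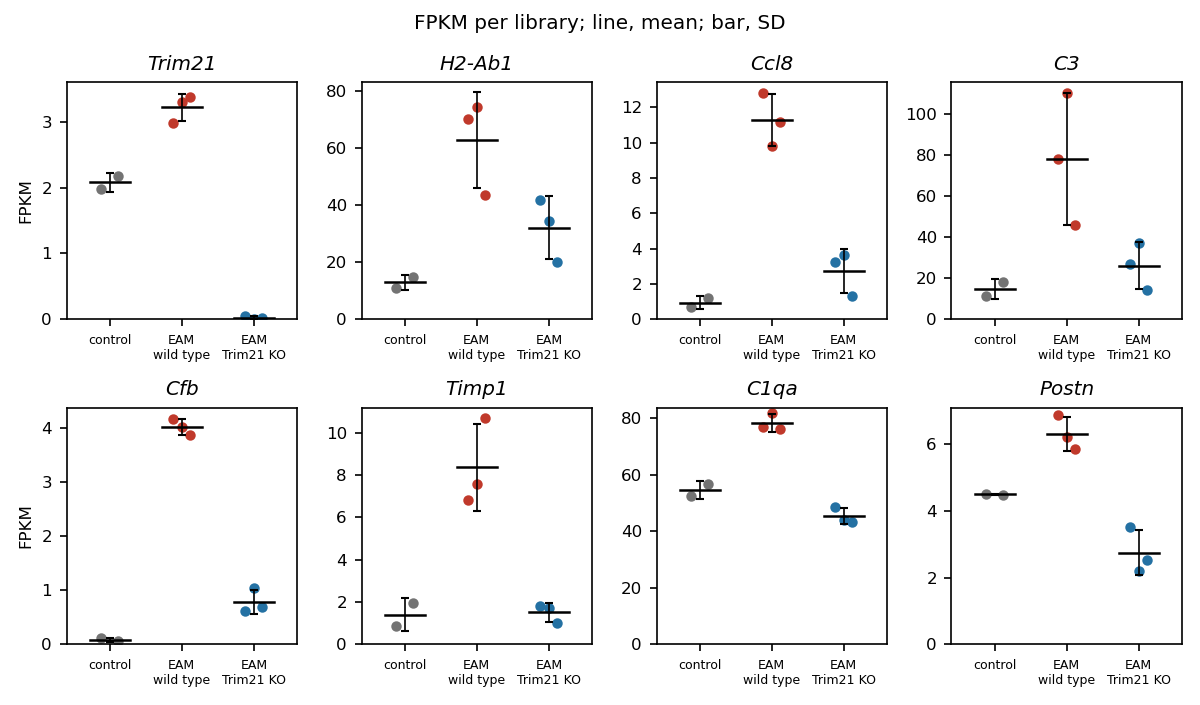
FPKM of 8 genes per library (points), with the group mean (line) and SD (bar), in control (n = 2), EAM wild type (n = 3) and EAM Trim21 KO (n = 3) hearts; each vertical axis starts at 0. Trim21 lies at 0 to 0.0481 FPKM in the knockout libraries, and Ccl8 and Timp1 have their highest values in EAM wild type.

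The comparison of EAM wild type with control hearts asked what the disease model changes in the wild-type heart. Genes of antigen presentation, chemokines and complement were higher in EAM. The MHC class II genes H2-Eb1, H2-Aa and H2-Ab1, which present peptides to helper T cells, rose from 18.4 ± 3.89, 10.6 ± 2.08 and 13.1 ± 2.66 FPKM (SD, n = 2) to 92.4 ± 19.7, 51.5 ± 10.6 and 62.7 ± 16.8 FPKM (SD, n = 3). Ccl8, a chemokine that attracts monocytes, rose from 0.946 ± 0.356 to 11.3 ± 1.48 FPKM, the largest log2 change among the named genes that passed (2.66, SE 0.27, limma adjusted p = 0.00479). The transcription factor gene Zbtb16 fell from 10.7 ± 4.56 to 1.84 ± 0.267 FPKM (log2 change -1.98, SE 0.22, limma adjusted p = 0.00479).

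All 8 tested MHC class II presentation genes had positive changes, with a median log2 change of 1.63. Of them, 7 rose over all genes tested and 8 when adjusted over the list alone (limma camera adjusted p = 7.45e-13; adjusted p = 0.111 with an estimated correlation). Cd74, the invariant chain, went from 89.0 ± 26.7 to 291 ± 69.4 FPKM. H2-Ea-ps, a class II alpha chain gene named as a pseudogene after the reference strain and functional in Balb/c mice, went from 30.9 ± 3.44 to 142 ± 19.7 FPKM. Of 10 MHC class I presentation genes, 6 rose, and 10 when adjusted over the list alone (limma camera adjusted p = 3.92e-13; adjusted p = 0.0864 with an estimated correlation). Among these were B2m, the class I light chain, at 267 ± 21.3 against 786 ± 95.4 FPKM, and the immunoproteasome gene Psmb8, at 2.93 ± 0.0473 against 9.07 ± 0.406 FPKM. The class I gene H2-Q6, named by its size of change, rose from 3.09 ± 0.552 to 18.5 ± 3.43 FPKM.

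Interferon response genes were higher at all 22 tested members, 7 of them past the threshold and 18 when adjusted over the list alone (limma camera adjusted p = 5.03e-14; adjusted p = 0.111 with an estimated correlation). The GTPase gene Igtp rose from 1.79 ± 0.0807 to 11.6 ± 2.58 FPKM, and Irf1, a transcription factor induced by interferon, from 2.93 ± 0.6 to 7.07 ± 0.569 FPKM. Of 15 chemokine genes, 5 rose (Ccl5, Ccl7, Ccl8, Cxcl9 and Cxcl16), and 10 when adjusted over the list alone (limma camera adjusted p = 9.2e-09; adjusted p = 0.0536 with an estimated correlation). Of 16 complement and Fc receptor genes, 4 rose, and 15 when adjusted over the list alone (limma camera adjusted p = 1.96e-12; adjusted p = 0.111 with an estimated correlation). C3, the central complement component, went from 14.9 ± 4.87 to 78.1 ± 32.3 FPKM, with a call lost under 12 of 22 alternatives, and complement factor B, Cfb, from 0.0837 ± 0.0383 to 4.02 ± 0.15 FPKM.

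Of 14 monocyte and macrophage markers, 3 rose (Adgre1, Lyz2 and Cx3cr1), and 10 rose and 1 fell when adjusted over the list alone (limma camera adjusted p = 1.79e-06; adjusted p = 0.111 with an estimated correlation). Lyz2, which encodes lysozyme, went from 126 ± 15.2 to 260.4 ± 29.5 FPKM. Markers of resident cardiac macrophages were lower as a list, with a median log2 change of -0.30 over 7 genes, none past the threshold and 2 lower when adjusted over the list alone (limma camera adjusted p = 0.00612; adjusted p = 0.111 with an estimated correlation). Lyve1, a hyaluronan receptor of resident macrophages and lymphatic vessels, was at 5.83 ± 0.422 in control and 2.53 ± 0.742 FPKM in EAM (limma adjusted p = 0.0711). T cell, dendritic cell, neutrophil and inflammatory cytokine lists had only 3, 3, 3 and 4 tested genes and were each higher as a list (limma camera adjusted p = 0.00413, 0.0041, 0.00202 and 0.00539; adjusted p = 0.111, 0.111, 0.154 and 0.111 with an estimated correlation). Over all genes Cd3g, Cd209a and Il1b rose, and no neutrophil marker passed. When adjusted over the list alone, 3, 2, 3 and 2 genes passed in that order. Il1b, the gene of interleukin-1β, was at 0.162 ± 0.0160 in control and 2.02 ± 0.598 FPKM in EAM. The calls of Cx3cr1, Cd3g and Lyz2 were lost under 15, 14 and 11 alternatives. Without control 2 the list of resident cardiac macrophage markers did not pass (limma camera adjusted p = 0.15), and without control 1 neither did inflammatory cytokines and inflammasome (limma camera adjusted p = 0.0794).

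The genes of fibroblasts and matrix were higher as lists. Of 18 myofibroblast and fibrosis genes Timp1 rose, and 11 when adjusted over the list alone (limma camera adjusted p = 2.3e-05; adjusted p = 0.271 with an estimated correlation). Timp1, an inhibitor of matrix metalloproteinases, went from 1.41 ± 0.785 to 8.37 ± 2.04 FPKM. Of 10 matrix remodelling genes, Mmp14 and Timp1 rose, Mmp14 with a call lost under 17 of 21 alternatives, and 5 when adjusted over the list alone (limma camera adjusted p = 0.00081; adjusted p = 0.111 with an estimated correlation). Of 14 fibroblast markers Col3a1, a fibrillar collagen gene, rose from 21.6 ± 0.322 to 55.3 ± 9.35 FPKM, and 4 genes when adjusted over the list alone (limma camera adjusted p = 0.00413; adjusted p = 0.509 with an estimated correlation). Immediate early genes were higher at all 12 tested members, with Jun and Egr1 past the threshold, calls lost under 15 and 16 of 22 alternatives, and 7 when adjusted over the list alone (limma camera adjusted p = 6.93e-06; adjusted p = 0.203 with an estimated correlation). The atrial list had the largest median log2 change of the lists tested here, 2.095 (mean 3.01), and the endothelial and lysosome lists were also higher, all 3 with no gene past the threshold (limma camera adjusted p = 0.0487, 0.00565 and 0.041; adjusted p = 0.615, 0.154 and 0.594 with an estimated correlation). When adjusted over the list alone, 0, 3 and 2 of their genes passed in that order. Without EAM wild type 1 neither fibroblast markers nor endothelial markers passed (limma camera adjusted p = 0.0657 and 0.0769), and with the atrial score as a covariate the fibroblast markers did not pass either (limma camera adjusted p = 0.287). Leaving out any library except knockout 1 ended the call of the lysosome genes (limma camera adjusted p from 0.0515 to 0.13). The call of the atrial genes ended without EAM wild type 1 or 2 or without either control (limma camera adjusted p = 0.062, 0.347, 0.162 and 0.0543).

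Heart muscle and mitochondrial lists were lower in EAM wild type by small amounts, and none of their genes passed, whether over all genes or adjusted over the list alone. All 15 contractile genes had negative changes with a median of -0.23 (limma camera adjusted p = 1.93e-08; adjusted p = 0.111 with an estimated correlation). Median changes were -0.19 for nuclear-encoded oxidative phosphorylation genes, -0.24 for fatty acid oxidation genes and -0.23 for mitochondrially encoded genes (limma camera adjusted p = 4.13e-07, 2.13e-06 and 0.000676; adjusted p = 0.327, 0.375 and 0.375 with an estimated correlation). Erythrocyte genes were lower as well, with a median of -0.37 over 5 genes (limma camera adjusted p = 0.0148; adjusted p = 0.374 with an estimated correlation). The 7 falling genes that met the naming rule were Zbtb16, Adh1, Timp4, Map3k6, Prodh, Sult1a1 and Vsig2. Adh1, an alcohol dehydrogenase gene, went from 16.3 ± 0.0742 to 6.49 ± 0.45 FPKM, and Timp4 from 17.8 ± 3.32 to 7.32 ± 2.36 FPKM. Without EAM wild type 3, which had the lowest mitochondrial share, the mitochondrially encoded genes did not pass, nor with quantile normalization (limma camera adjusted p = 0.505 and 0.362). The erythrocyte genes did not pass without that library or without control 2 (limma camera adjusted p = 0.0841 and 0.209), and scaling by median ratios ended their call as well.

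Of 10393 genes tested with limma, 141 rose and 14 fell in EAM wild type, 62 and 8 of them by at least 2-fold, and 1514 had an unadjusted p under 0.05. The counts moved with the controls, to 13 up and 2 down without control 1 and 48 up and 8 down without control 2, and to 65 up without EAM wild type 1 and 71 up and 8 down without EAM wild type 2. Scaling by median ratios gave 74 up and 19 down, and quantile normalization 58 up and 17 down. Without the 3 libraries high in atrial transcripts, 50 genes rose and 4 fell. Of the 17 genes named by size, 14 lost their call when some library was left out; H2-Q6, H2-Ea-ps and Zbtb16 kept it under all 22 settings.

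The comparison of EAM Trim21 KO with EAM wild type hearts asked how loss of Trim21 changes the diseased heart. Complement, macrophage, antigen presentation and matrix genes were lower in the knockout. Cfb fell from 4.02 ± 0.15 to 0.784 ± 0.223 FPKM (SD, n = 3 each), Timp1 from 8.37 ± 2.04 to 1.52 ± 0.441 FPKM, and Ccl8 from 11.3 ± 1.48 to 2.74 ± 1.24 FPKM. Circadian clock genes changed in opposite directions, with Arntl at 1.37 ± 0.567 against 7.99 ± 0.693 FPKM and Dbp at 29.97 ± 2.71 against 2.25 ± 0.817 FPKM. The inducible heat shock genes Hspa1a and Hspa1b fell from 50.4 ± 47.0 and 47.4 ± 43.3 FPKM to 1.01 ± 0.611 and 0.667 ± 0.235 FPKM.

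The median log2 change of all tested genes was -0.116 in this comparison, and 0.004 after scaling by median ratios. Each change below is given as fitted and is about that much smaller in size, for a fall, relative to all genes. The camera test compares a list with all other genes, yet scaling ended 3 of its calls in this comparison, those of the mast cell and eosinophil, mitochondrially encoded and oxidative phosphorylation lists. All lists named as lower here kept a negative median under each of the 4 other scalings tried.

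All 16 tested complement and Fc receptor genes had negative changes with a median of -0.72, and 7 fell (C1qa, C1qb, C1qc, C1ra, Cfb, Fcgr2b and Fcgr4), or 14 when adjusted over the list alone (limma camera adjusted p = 2.85e-08; adjusted p = 0.209 with an estimated correlation). C1qa, which encodes a chain of the first complement component, went from 78.3 ± 3.06 to 45.4 ± 2.87 FPKM (log2 change -0.78, SE 0.11, limma adjusted p = 0.00986). Of 14 monocyte and macrophage markers, 6 fell, and 10 when adjusted over the list alone (limma camera adjusted p = 4.58e-06; adjusted p = 0.206 with an estimated correlation). Among them, Cd68, a lysosomal protein of macrophages, went from 9.47 ± 0.409 to 5.32 ± 0.226 FPKM and Lyz2 from 260.4 ± 29.5 to 138 ± 23.5 FPKM. The calls of Cd68 and C1qb were lost under 3 and 7 of 22 alternatives, for both genes including median-ratio scaling and quantile normalization. Resident cardiac macrophage markers did not pass, with a median of 0.03 over 7 genes that turned to -0.0057 with equal FPKM sums (limma camera adjusted p = 0.370). Of 3 tested dendritic cell markers, Itgax and Cd209a fell, also when adjusted over the list alone (limma camera adjusted p = 0.0307; adjusted p = 0.222 with an estimated correlation). The dendritic cell markers did not pass without EAM wild type 1, without the 3 libraries high in atrial transcripts or with a pseudocount of 5 (limma camera adjusted p = 0.0948, 0.0643 and 0.087). Cd209a lost its call under 13 alternatives and Itgax under 9. Of 15 lysosome genes Npc2 fell, with a call lost under 15 of 22 alternatives that include each of the 4 other scalings, and 8 when adjusted over the list alone (limma camera adjusted p = 0.00533; adjusted p = 0.468 with an estimated correlation).

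All 8 tested MHC class II presentation genes had negative changes with a median of -0.98. Of these, 4 fell (H2-DMa, H2-DMb1, Cd74 and Ctss), and 8 when adjusted over the list alone (limma camera adjusted p = 6.08e-06; adjusted p = 0.308 with an estimated correlation). H2-Ab1 was at 62.7 ± 16.8 against 32.1 ± 11.1 FPKM and did not pass (limma adjusted p = 0.104). The calls of Ctss, H2-DMb1 and H2-DMa were lost under 9, 8 and 6 alternatives, for all of them including median-ratio scaling and quantile normalization. H2-Ea-ps fell from 142 ± 19.7 to 34.5 ± 6.86 FPKM. Of 10 MHC class I presentation genes, B2m and Psmb8 fell, with calls lost under 10 and 1 of 22 alternatives, and 8 when adjusted over the list alone (limma camera adjusted p = 1.21e-05; adjusted p = 0.201 with an estimated correlation). Of 22 interferon response genes, 5 fell, and 9 when adjusted over the list alone (limma camera adjusted p = 9.69e-05; adjusted p = 0.358 with an estimated correlation). Igtp was at 4.11 ± 1.60 FPKM in the knockout. Without the 3 libraries high in atrial transcripts the interferon response genes did not pass (limma camera adjusted p = 0.788). Of 15 chemokine genes, 5 fell (Ccl5, Ccl7, Ccl8, Cxcl9 and Cxcl16), and 8 when adjusted over the list alone (limma camera adjusted p = 0.000356, and adjusted p = 0.133 with an estimated correlation). Cxcl16 lost its call under 9 of 22 alternatives, among them median-ratio scaling and quantile normalization.

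For IL-17 signalling, 9 response genes were tested and Ccl7 fell, or 4 genes when adjusted over the list alone (limma camera adjusted p = 0.00848; adjusted p = 0.201 with an estimated correlation). The same list was higher in EAM wild type than in control, with Ccl7 past the threshold and 6 up and 1 down when adjusted over the list alone (limma camera adjusted p = 0.00822; adjusted p = 0.111 with an estimated correlation). Against control, the IL-17 response genes did not pass without EAM wild type 1, without control 2 or among genes with an FPKM of at least 5 (limma camera adjusted p = 0.062, 0.0521 and 0.809). Between the genotypes, the list did not pass among genes with an FPKM of at least 5 (limma camera adjusted p = 0.0608). The fall of Ccl7 lost its call under 15 of 22 alternatives, among them median-ratio scaling, quantile normalization and the omission of any library except EAM wild type 2. Its rise against control lost its call under 14 of 22. Ccl7, a monocyte chemokine, was at 0.926 ± 0.371 FPKM in control, 8.15 ± 5.03 in EAM wild type and 1.48 ± 0.352 in EAM knockout. None of 13 tested IL-17 receptor and signalling genes passed in either comparison, nor when adjusted over the list alone (limma camera adjusted p = 0.0795 against control and 0.625 between genotypes). Fry, which tests whether genes of a list move one way and does not compare them with other genes, passed this list in both comparisons (limma fry adjusted p = 0.0225, 12 of 13 genes higher in EAM wild type; adjusted p = 0.0478, 10 of 13 lower in the knockout). This list had median changes of 0.20 and -0.15 in the 2 comparisons, where the medians of all tested genes were 0.08 and -0.12. Its scores per library did not overlap between the genotypes (exact two-sided permutation p = 0.1, adjusted 0.183). Il17a itself was listed at 0 in all 8 libraries, where 3 fragments would correspond to 0.151 to 0.178 FPKM, so its level was not detectable at this depth. Il6 was listed at 0 in knockout and control libraries and at 0.153, 0.0958 and 0.0337 FPKM in EAM wild type, the last 2 of these from about 3.6 and 1.2 fragments. Traf3 was below the expression filter, with means of 0.498 ± 0.506 FPKM in control, 0.508 ± 0.290 in EAM wild type and 0.561 ± 0.395 in EAM knockout. Traf6 was at 1.60 ± 0.0966 in EAM wild type and 1.40 ± 0.108 FPKM in EAM knockout (limma adjusted p = 0.531).

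All 18 myofibroblast and fibrosis genes had negative changes with a median of -0.58, and 6 fell (Postn, Col5a1, Col8a1, Loxl2, Timp1 and Sfrp1), or 12 when adjusted over the list alone (limma camera adjusted p = 8.68e-08; adjusted p = 0.222 with an estimated correlation). Postn, the matrix protein periostin, went from 6.32 ± 0.507 to 2.76 ± 0.684 FPKM (log2 change -0.98, SE 0.13, limma adjusted p = 0.00874). Of 14 fibroblast markers, 3 fell (Dcn, Lum and Col3a1, whose calls were lost under 11, 4 and 5 alternatives), and 9 when adjusted over the list alone (limma camera adjusted p = 6.08e-06; adjusted p = 0.358 with an estimated correlation). Of 10 matrix remodelling genes, 5 fell, among them Timp1 and Ctsk, and 6 when adjusted over the list alone (limma camera adjusted p = 8.5e-06; adjusted p = 0.133 with an estimated correlation). Ctsk, a collagen-degrading protease gene, went from 7.15 ± 1.17 to 2.94 ± 0.351 FPKM. Endothelial markers did not pass, with a median of -0.12 that lies at the median of all genes and turned to 0.04 with median-ratio scaling and 0.02 with quantile normalization (limma camera adjusted p = 0.744).

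Of 14 circadian clock genes, Arntl and Npas2, which form the activating arm of the clock, rose. Another 9 fell (Per1, Per2, Per3, Cry2, Nr1d2, Dbp, Tef, Ciart and Bhlhe41), so 11 genes passed over all genes and 13 when adjusted over the list alone (limma camera adjusted p = 6.08e-06; adjusted p = 0.133 with an estimated correlation). Per2 went from 7.10 ± 3.08 to 0.570 ± 0.416 FPKM and Per1 from 10.3 ± 1.72 to 2.12 ± 0.182 FPKM. In EAM wild type against control no clock gene passed over all genes, and 1 up and 1 down when adjusted over the list alone (limma camera adjusted p = 0.688). Of 8 heat shock genes, Hspa1a, Hspa1b and Dnajb1 fell, and 7 when adjusted over the list alone (limma camera adjusted p = 1.45e-05; adjusted p = 0.224 with an estimated correlation). Of 9 fetal and stress genes of the heart, Nppb, Ankrd1 and Gdf15 fell, and 7 when adjusted over the list alone (limma camera adjusted p = 0.0008; adjusted p = 0.137 with an estimated correlation). Nppb, the B-type natriuretic peptide gene, went from 808 ± 179 to 448 ± 59.4 FPKM, with a call lost under 11 of 22 alternatives, and Gdf15 lost its call under 13.

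**Figure D2:**
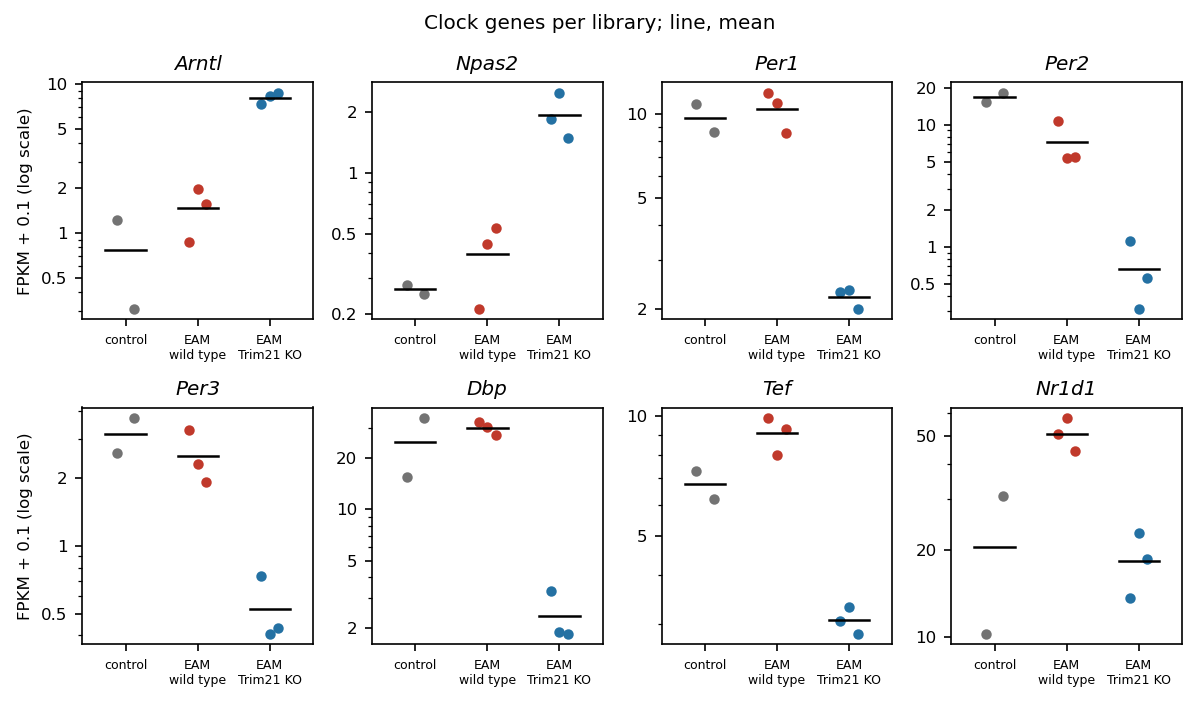
FPKM plus 0.1 (log axis) of 8 clock genes per library (points), with the group mean (line), in control (n = 2), EAM wild type (n = 3) and EAM Trim21 KO (n = 3) hearts. Arntl and Npas2 have their highest values in the knockout and Per1, Per2, Per3, Dbp and Tef their lowest.

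Higher lists in the knockout were cardiac calcium and ion channel genes, mitochondrially encoded genes and adipocyte genes, with medians of 0.30, 0.24 and 0.79 (limma camera adjusted p = 1.12e-06, 5.98e-06 and 0.000515; adjusted p = 0.309, 0.317 and 0.419 with an estimated correlation). No mitochondrially encoded or adipocyte gene passed, over all genes or adjusted over the list alone. The mitochondrially encoded genes lost their call with quantile normalization and without EAM wild type 3 (limma camera adjusted p = 0.466 and 0.117). The adipocyte genes lost theirs without knockout 1 and without the 3 libraries high in atrial transcripts (limma camera adjusted p = 0.0957 and 0.412). Fatty acid oxidation, oxidative phosphorylation, glycolysis and mast cell and eosinophil lists also passed (limma camera adjusted p = 0.00857, 0.0386, 0.0314 and 0.0134; adjusted p = 0.605, 0.672, 0.383 and 0.206 with an estimated correlation). Their medians were 0.03, 0.0013, -0.05 and 0.34, so the glycolysis list stood above other genes while its own median was negative. Of its 14 genes 6 were higher and 8 lower, and Gapdh alone changed by 2.46 against a list mean of 0.136. The glycolysis list was not tested without Gapdh. With median-ratio scaling all 4 medians were positive, and with equal FPKM sums the fatty acid oxidation, oxidative phosphorylation and glycolysis medians were negative. Gapdh was the only member of these 4 lists past the threshold, over all genes and adjusted over the list alone. Each of these 4 lists lost its call without at least 1 library, with limma camera adjusted p up to 0.208 for fatty acid oxidation (without EAM wild type 1 or knockout 3), 0.403 for oxidative phosphorylation, nuclear encoded (without EAM wild type 1 or 2 or knockout 3), 0.0948 for glycolysis (without EAM wild type 1 or 3 or knockout 3) and 0.0546 for mast cell and eosinophil markers (without EAM wild type 2 or knockout 3). The mast cell and eosinophil markers also lost their call with median-ratio scaling and quantile normalization (limma camera adjusted p = 0.0807 and 0.0821), and oxidative phosphorylation with equal FPKM sums (limma camera adjusted p = 0.111). Ribosomal protein genes were lower as a list with a median of -0.31, none of 21 past the threshold and none when adjusted over the list alone (limma camera adjusted p = 0.0279; adjusted p = 0.672 with an estimated correlation). Without knockout 2, knockout 3, EAM wild type 1 or EAM wild type 3, the ribosomal proteins did not pass (limma camera adjusted p from 0.069 to 0.198).

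**Figure D3:**
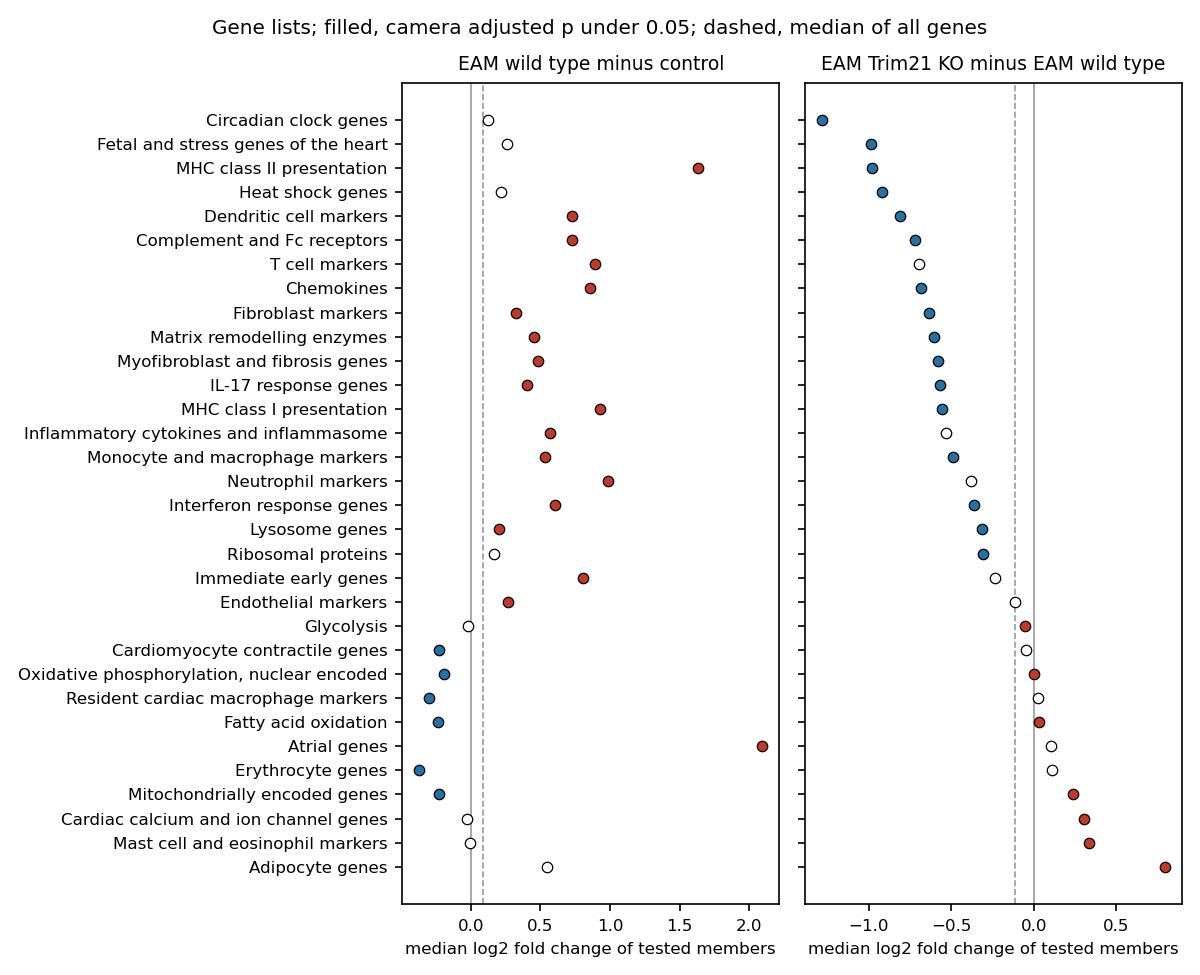
Median log2 fold change of the tested members of 32 gene lists (one row each) in EAM wild type minus control (left) and EAM Trim21 KO minus EAM wild type (right). Filled points passed camera (red, median above that of all genes; blue, below), open points did not, and the dashed line marks the median of all genes, at 0.08 and -0.12; the MHC class II list lies at 1.63 on the left and -0.98 on the right.

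Several of the most changed genes were far apart between the genotypes in every library, and Rpl29 and Aqp6 were below 1 FPKM in one of them. Rpl29, a ribosomal protein gene on chromosome 9 from 106429454 to 106431568, was at 0.425 ± 0.169 FPKM in EAM wild type and 49.2 ± 1.70 FPKM in the knockout (log2 change 5.14, SE 0.12, limma adjusted p = 9.09e-08). Gapdh, a glycolysis gene on chromosome 6 from 125161715 to 125166467, was at 3.46 ± 0.575 and 23.3 ± 0.613 FPKM. The water channel gene Aqp6, on chromosome 15 from 99601400 to 99605477, was at 23.4 ± 3.14 and 0.0108 ± 0.0187 FPKM, and Dynlt1b, on chromosome 17 from 6430112 to 6436293, at 12.9 ± 1.70 and 1.39 ± 0.0315 FPKM. The beta globin gene Hbb-bt, on chromosome 7 from 103812524 to 103813996, rose from 11.6 ± 3.38 to 65.1 ± 8.78 FPKM, while its near-identical neighbour Hbb-bs was at 104 ± 37.9 and 55.1 ± 7.84 FPKM (limma adjusted p = 0.0782). Control hearts had 0.628 ± 0.240 FPKM of Rpl29, 2.97 ± 1.01 of Gapdh, 30.2 ± 5.35 of Aqp6, 12.7 ± 2.47 of Dynlt1b and 15.7 ± 9.94 of Hbb-bt. Rpl29, Gapdh, Dynlt1b and Hbb-bt have pseudogenes or close copies that can share reads, so their levels are uncertain. The other rising genes named by size were Arntl, Pcp4l1, Lingo3, Nfil3, Rrad, Ces1d and Dusp23.

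Of 10393 genes tested with limma, 30 rose and 291 fell in the knockout, 16 and 64 of them by at least 2-fold, and 2075 had an unadjusted p under 0.05. Scaling by median ratios gave 46 up and 85 down and quantile normalization 57 up and 98 down, and without the 3 libraries high in atrial transcripts 12 genes rose and 33 fell. The count of falling genes was 72 without knockout 2, 80 without EAM wild type 1, 116 without knockout 3, 163 without EAM wild type 2 and 184 without EAM wild type 3, and the count of rising genes was 49 without knockout 3. Per-list mean expression scores separated the 3 knockout from the 3 EAM wild-type libraries in 23 of 42 lists. Each of these had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 can give. Chance separates 10% of lists on average. Some lists share genes and all share the same libraries, so they are not independent and the excess over 10% cannot be weighed.

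The comparison of EAM Trim21 KO with control combined genotype, disease and day. Clock genes differed here as well. Per2 fell from 16.6 ± 1.83 FPKM in control (SD, n = 2) to 0.570 ± 0.416 in EAM knockout (SD, n = 3), and Arntl rose from 0.665 ± 0.642 to 7.99 ± 0.693 FPKM. Zbtb16 fell to 1.51 ± 0.351 FPKM, and Fam46b from 10.7 ± 1.12 to 1.48 ± 0.794 FPKM. The early response gene Egr1 rose from 1.93 ± 0.191 to 10.3 ± 1.93 FPKM, and Rrad, a small GTPase gene of muscle, from 29.7 ± 7.65 to 134 ± 3.76 FPKM.

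Antigen presentation remained above control as lists. MHC class I genes had a median of 0.45, class II genes of 0.70 and interferon response genes of 0.31, with no gene past the threshold over all genes and 6, 6 and 0 when adjusted over the list alone (limma camera adjusted p = 2.38e-06, 2.28e-06 and 5.26e-07; adjusted p = 0.244, 0.319 and 0.319 with an estimated correlation). H2-Q6, outside these lists, rose from 3.09 ± 0.552 to 12 ± 1.58 FPKM. Monocyte and macrophage markers and complement genes did not pass (limma camera adjusted p = 0.986 and 0.155), with Lyz2 at 126 ± 15.2 against 138 ± 23.5 FPKM, although Cfb rose (limma adjusted p = 0.0324). Of 14 clock genes, 2 rose and 8 fell, and 2 and 10 when adjusted over the list alone (limma camera adjusted p = 5.26e-07; adjusted p = 0.218 with an estimated correlation). Chemokine, immediate early, ion channel, endothelial, neutrophil, B cell, atrial and adipocyte lists were also higher (limma camera adjusted p from 0.000664 to 0.0193; adjusted p from 0.244 to 0.540 with an estimated correlation). Of their genes only Fos and Egr1, of the immediate early list, and Kdr, an endothelial growth factor receptor gene, passed, with calls lost under 15, 3 and 8 of 22 alternatives. When adjusted over the list alone, 1 chemokine, 4 immediate early (and 1 lower), 3 ion channel, 2 endothelial, 1 neutrophil, 1 B cell, 0 atrial and 0 adipocyte genes passed. Heat shock, contractile, fetal and stress, and oxidative phosphorylation lists were lower (limma camera adjusted p from 7.86e-05 to 0.00845; adjusted p from 0.244 to 0.696 with an estimated correlation), with 6, 1, 3 and 0 genes lower when adjusted over the list alone. With quantile normalization the cardiomyocyte contractile genes, oxidative phosphorylation, nuclear encoded, the neutrophil markers and the chemokines did not pass (limma camera adjusted p = 0.407, 0.635, 0.114 and 0.0885). Without control 1 the chemokines, neutrophil markers and B cell and plasma cell markers did not pass (limma camera adjusted p = 0.205, 0.149 and 0.0574). Without the 3 libraries high in atrial transcripts, the atrial genes, adipocyte genes, B cell and plasma cell markers and oxidative phosphorylation did not pass (limma camera adjusted p = 0.954, 0.371, 0.118 and 0.326). Among contractile genes Tcap, a protein of the sarcomere's Z-disc, fell from 2218 ± 167 to 899 ± 134 FPKM, and the skeletal actin gene Acta1 fell from 5437 ± 409 to 1839 ± 673 FPKM, with calls lost under 3 and 8 of 22 alternatives.

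Of 10393 genes tested with limma, 59 rose and 83 fell against control, 28 and 40 of them by at least 2-fold, and 1422 had an unadjusted p under 0.05. Median-ratio scaling gave 73 up and 74 down, and without the 3 libraries high in atrial transcripts 18 rose and 22 fell. The counts were 17 up and 21 down without control 1, 11 up and 24 down without control 2, 27 up and 38 down without knockout 2, 36 up without knockout 1 and 93 up without knockout 3.

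The relation of the disease change to the genotype change was examined across genes. Of the 141 genes that rose in EAM wild type, 71 fell in EAM knockout against EAM wild type, among them H2-Ea-ps, Dnajb1, Timp1, Ccl8, Ccl7 and Cfb, while independent lists would share 3.95. For 133 of the 141 genes (94.3%) the knockout mean was nearer to control than the EAM wild-type mean was, with a median ratio of 0.386 between the knockout and wild-type changes from control. Against control, 21 of the 141 also rose in EAM knockout, where independent lists would share 0.8. Of the 14 genes that fell in EAM wild type, 10 also fell in EAM knockout against control, where independent lists would share 0.112. The EAM wild-type libraries enter both sides of the relation between the rise and the fall, and the controls both sides of the overlaps against control, so part of each excess may come from shared libraries. Genes were therefore chosen again with each EAM wild-type library held out. The knockout mean was below the held-out wild-type library in 86.2%, 90.1% and 78.6% of the 65, 71 and 112 genes so chosen, with median log2 differences of -0.55, -0.67 and -0.49. It was also below the held-out library in 80%, 75% and 84.6% of the 15, 8 and 13 genes chosen as falling, so the knockout was lower for most of the chosen genes whichever way the disease change went. Of the 14 falling genes, 5 (35.7%) had a knockout mean nearer to control, with a median ratio of 1.23. Across all tested genes, which are not independent replicates, the changes correlated with r = -0.334, against -0.377 ± 0.430 (SD, 100 draws) in simulations of unchanged groups that share the same libraries. The covariance was -0.0313 against -0.0167 ± 0.0236 simulated, so the relation over all genes did not exceed what shared libraries give.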

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

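The fits without the 3 libraries high in atrial transcripts (EAM knockout 1 and 2 and EAM wild type 2) and with an atrial score as covariate were chosen after the data were seen. The first of these leaves knockout 3 as the only knockout library, assumed to vary like the other groups. Depth limits what the low genes can show, since 3 fragments of Il17a equal 0.151 to 0.178 FPKM. The causes of the changes below were not tested, except that stricter filters tested fewer genes, left-out libraries leave fewer samples, and a 2-fold limit keeps only part of the same calls. Of the named-gene results recomputed under the alternatives, 4980 kept their side of the threshold. Another 524 kept their direction and no longer passed, and 100 kept it and came to pass. Among results that passed in the main or the alternative fit, 0 reversed. Where neither passed, the direction was not compared.

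In EAM wild type against control (141 up, 14 down), the genes that rose numbered 71 with no filter, 72 with an FPKM of at least 5, 74 with median-ratio scaling, 58 with quantile normalization, 333 with library weights and 91 with only the 2 groups fitted. They numbered 50 without the 3 libraries high in atrial transcripts, 47 with the atrial covariate and 62 at 2-fold. The genes that fell numbered 5 with an FPKM of at least 5, 53 with weights, 8 with 2 groups, 9 with the replicate number as a block, 4 without the 3 libraries, 7 with the covariate and 8 at 2-fold. Leaving out 1 library gave 13 (without control 1) to 115 up and 2 (without control 1) to 15 down. Without EAM wild type 1, EAM wild type 2 and control 2 the counts up were 65, 71 and 48, and without each of the last 2 of these 8 genes fell. Leaving out control 1 or 2 leaves 1 control, which is assumed to vary like the other groups. Of the lists, 18 were higher and 6 lower. Their numbers were 0 and 0 with an estimated correlation, 1 was lower by fry, and leaving out 1 library gave 14 to 21 higher and 4 to 8 lower.

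In EAM knockout against EAM wild type (30 up, 291 down), the genes that fell numbered 147 with no filter, 178 with an FPKM of at least 5, 85 with median-ratio scaling, all of them among the 291, 174 with equal FPKM sums without mitochondrially encoded genes and 98 with quantile normalization. They numbered 460 with weights, 33 without the 3 libraries and 64 at 2-fold. The genes that rose numbered 17 with an FPKM of at least 5, 46 with median-ratio scaling, which held all 30, 57 with quantile normalization, 12 without the 3 libraries, 47 with the covariate and 16 at 2-fold. Leaving out 1 library gave 20 to 49 (without knockout 3) up and 72 (without knockout 2) to 211 down. The counts down were 116 without knockout 3 and 80, 163 and 184 without EAM wild type 1, 2 and 3. Of the lists, 7 were higher and 16 lower. With no filter 4 were higher, with an estimated correlation 0 and 0 passed, by fry 0 were higher, and leaving out 1 library gave 6 to 8 higher and 15 to 16 lower.

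In EAM knockout against control (59 up, 83 down), the counts up and down were 25 and 48 with no filter, 24 and 51 with an FPKM of at least 5, 129 and 214 with weights, 18 and 22 without the 3 libraries, 19 and 32 with the covariate, and 28 and 40 at 2-fold. Leaving out 1 library gave 11 (without control 2) to 93 (without knockout 3) up and 21 (without control 1) to 100 down. Counts up were 36, 27 and 17 without knockout 1, knockout 2 and control 1, and counts down 38 and 24 without knockout 2 and control 2. Of the lists, 11 were higher and 5 lower. With an FPKM of at least 5, 7 were higher, with quantile normalization 3 were lower, with an estimated correlation 0 and 0 passed, by fry 2 were higher and 3 lower, and leaving out 1 library gave 8 to 16 higher and 5 to 8 lower. The correlation across genes of the disease change with the genotype change was -0.334, and -0.44 (without EAM wild type 3) to -0.18 (without knockout 3).

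Of the genes named by size in the 3 comparisons, 3 of 17, 7 of 20 and 10 of 20 kept their call under all 22 alternatives. In EAM knockout against EAM wild type these were Aqp6, Dbp, Dynlt1b, Gapdh, Per1, Per2 and Rpl29, and of the 32 genes named otherwise 4 (Trim21, Ccl8, Cfb and Tef) kept theirs under every alternative that tested them. Of those 32, 16 lost their call under a scaling and 24 without some library; in EAM wild type against control 2 of 21 such genes kept it and in EAM knockout against control 1 of 4. Of the 20 genes named by size, Ces1d and Pcp4l1 lost their call under a scaling and 4 without some library. Whether libraries of the same replicate number are related was not settled. Deviations from group means correlated above 0.1 in 2 of 7 same-number pairs and 6 of 14 others. The 2 highest values were knockout 2 with EAM wild type 2 (0.355) and knockout 3 with EAM wild type 3 (0.311). Knockout 1 with EAM wild type 1 gave -0.09, and the highest value among pairs of unlike number was 0.256. The 2 controls deviate in opposite ways by construction, so pairs with them add little.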

Other observations

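Among the tests here, those of dilution, of the time of day, of the position of genes far apart between the genotypes, and of the strain background were chosen after the results they bear on were seen.

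Genes that respond to glucocorticoids were among the genes lower in both EAM groups than in control. Zbtb16, Fkbp5 and Fam107a, all induced by glucocorticoids, were at 10.7, 3.92 and 3.61 FPKM in control, 1.84, 1.42 and 0.98 in EAM wild type and 1.51, 0.922 and 0.453 in EAM knockout. Fkbp5 and Fam107a, chosen after their values were seen, changed by -1.03 and -1.20 on the log2 scale in EAM wild type against control (limma adjusted p = 0.00898 and 0.00561). A hypothesis is a lower glucocorticoid signal in the EAM hearts, and 10 further responsive genes were written down before they were looked at as a list. Sult1a1, written down with them, was left out because it had been seen in the main test. Cebpd belongs to the fixed IL-17 response list as well and had been tested there. Their list was lower in EAM wild type than in control (limma camera p = 0.0186, median log2 change -0.157), with 6 of the 10 genes lower and 4 higher (Sgk1, Errfi1, Cebpd and Nfkbia), none past the threshold, and a p of 0.219 with an estimated correlation. In EAM knockout against control the median change of these genes was -0.395, and Tsc22d3 was at 17.5 FPKM in control and 8.08 in the knockout (limma adjusted p = 0.0414). The values are consistent with a lower glucocorticoid signal by the preset-correlation test alone, and handling or hour of collection of the controls may enter as well.

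Other lists add detail on cells and tissues. The T cell, neutrophil and inflammatory cytokine lists, higher in EAM wild type than in control, did not pass between the genotypes (limma camera adjusted p = 0.287, 0.307 and 0.245). Of their genes Cd3g and Il1b fell, and by fry the T cell and cytokine lists passed as lower (limma fry adjusted p = 0.0406 and 0.0186). B cell and plasma cell markers and Th17 genes did not pass between the genotypes either (limma camera adjusted p = 0.151 and 0.751). Of the regulatory T cell, NK cell and thymocyte lists 0 genes were tested. Nor did smooth muscle, endothelial activation, cell cycle, unfolded protein response, Schwann cell and fast skeletal muscle lists pass camera in any of the 3 comparisons. Their lowest limma camera adjusted p was 0.0691, for endothelial activation in EAM wild type against control. By fry that list passed there as higher (limma fry adjusted p = 0.0218), and smooth muscle passed as lower between the genotypes (limma fry adjusted p = 0.0406). Of 10 tested TRIM family members, Trim21 and Trim12c fell and Trim12a rose between the genotypes. Trim12c went from 2.40 to 1.36 FPKM (limma adjusted p = 0.0294), and Trim12a from 0 in each EAM wild-type library to 1.25 FPKM (limma adjusted p = 0.00123). Trim30a rose in EAM wild type against control (limma adjusted p = 0.0479). The adipocyte gene Adipoq averaged 0 FPKM in control, 1.49 ± 2.35 in EAM wild type and 4.22 ± 5.63 in EAM knockout. The atrial gene Myl4 was at 213.6, 167.5 and 157.4 FPKM in EAM knockout 1, EAM knockout 2 and EAM wild type 2 and at 0.476 to 29.03 in the other 5 libraries.

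Of the 10 splits of the 6 EAM libraries into 3 and 3, only 1, the real one, gave as many as 321 changed genes, and the highest of the others gave 46. That split set knockout 1, knockout 2 and EAM wild type 2, the libraries high in atrial transcripts, against the rest, which points to a structure of the samples beside genotype. With 10 splits no share under 0.05 can be had.

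The lower immune lists in the knockout were weighed against dilution, atrial content and time of day. Dilution by more heart muscle RNA would lower vascular genes alike. The immune minus vascular score differed by -0.517 (log2) between knockout and EAM wild type, with no overlap of the 3 and 3 libraries. Its 82 immune genes came from the complement, macrophage, antigen presentation, interferon, chemokine and dendritic cell lists, all chosen after passing as lower here. The vascular lists had not passed camera, though the smooth muscle and pericyte list passed fry as lower (limma fry adjusted p = 0.0406). The choice therefore favoured a negative and separated difference, and this score cannot exclude dilution. The median change was -0.569 in the immune and -0.128 in the vascular genes. With the atrial score as a covariate the median change of these 82 immune genes was -0.565, against -0.569 without it. The mean atrial score was similar in EAM knockout (5.09) and EAM wild type (4.88). The covariate could therefore hardly move this median and does not decide the question. Within the knockout libraries the atrial score ran from 1.74 to 7.06, while the mean of the immune genes stayed between 2.39 and 2.45. Single lists behind that mean moved in opposite ways. In knockout 1, 2 and 3, MHC class II genes scored 3.996, 3.903 and 3.472 and complement and Fc receptor genes 2.613, 2.684 and 2.303. Interferon response genes scored 1.715, 1.774 and 2.051, so the flat mean does not show that each list was unrelated to atrial content. A different time of day of collection cannot be told apart from genotype for these genes, since only 3 libraries per genotype exist and clock and genotype move together. A weaker immune infiltrate, a different course of disease by the day of collection, and the genetic background stay open as well.

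The clock genes were weighed against hearts collected at another time of day. All 14 tested members had the sign of an opposite-phase pattern, Arntl, Npas2 and Cry1 one way and the rest the other, but that pattern was written down after the 11 calls were seen and restates them, and Cry1, Nr1d1 and Hlf did not pass (limma adjusted p = 0.68, 0.0574 and 0.0616). The count therefore does not favour this explanation. A different hour of collection and a change of the clock itself in the knockout cannot be told apart, since no hour of collection is labelled and it would follow genotype in every library.

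Genes clearly apart between the EAM genotypes were weighed against DNA of another strain. The 26 such genes, Trim21 included, many of them present in both genotypes, passed limma and had every library of one EAM group at least 3 times above every library of the other (FPKM plus 0.1). Within 10 Mb of Trim21 lay 2 of them, Hbb-bt at 1.25 Mb and Trim12a at 1.75 Mb, where random placement gives 0.265 (one-sided Fisher's exact test p = 0.0284). DNA around the targeted locus from another strain would give such an excess. The test takes these 2 as independent placements although they lie close together, and the level of Hbb-bt is uncertain, so the p-value decides little. Whether DNA around the targeted locus acts on genes elsewhere was not tested, so position alone does not settle the 20 genes on other chromosomes. Among these are Rpl29, Gapdh, Aqp6 and Dynlt1b as well as Cfb and Timp1, which changed with disease. Some of these 20 lie close together. Pianp, on chromosome 6 from 124996694 to 125003096 near Gapdh, was at 3.98 in EAM wild type and 0.318 FPKM in the knockout. Tmem181b-ps, on chromosome 17 from 6438524 to 6467022 beside Dynlt1b, was at 2.14 and 0.19 FPKM. Arntl, on chromosome 7, lay 10.7 Mb from Trim21, just outside the limit of 10 Mb. Controls lay nearer EAM wild type than knockout for 76% of the 25 genes without Trim21 (14 of 20 without the clock list), so a wider strain difference or its effect on mapping to the reference cannot be told apart from genotype, which it follows in every library.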
